A study of Caenorhabditis elegans with 9 samples.

How the data were processed

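Small RNA libraries came from 9 samples of whole adult hermaphrodites, 3 each of wild type, prg-1 RNase-dead and prg-1 PAZ-deletion. Per the labels' protocols, small RNA was extracted with a mirVana kit, treated with acid pyrophosphatase so that RNAs with a 5′ triphosphate could be cloned, and made into libraries with a TruSeq small RNA kit. This treatment lets secondary siRNAs with a 5′ triphosphate enter the library beside piRNAs and microRNAs, and they are part of the genome-mapped reads used as the denominator. The growth text calls the animals both hermaphrodite and male, and hermaphrodite was used because the sample titles say so. Groups and replicate numbers were taken from the titles and genotype labels. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. For single entries and segments, edgeR used a spread largely pooled over all features. The spread of an entry's own libraries therefore enters its p and FDR only weakly, and a very small FDR is no measure of that entry's own replicate spread.

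The deposited values per piRNA were raw counts of sense and of antisense reads for each library, per the file headers, on 15913 piRNAdb entries of release 1.7.6. The deposited counts per genome segment were raw read counts too, per the file headers, and each column summed exactly to the total in its first row, which was left out of every test. Per the submitters' processing notes, FastQC 0.12.0 and cutadapt 3.7 were used. The aligner, its treatment of reads with several matches, and the genome build are not given in the sources used here. piRNAdb entries with near-identical sequences can therefore share reads, and the level of a single entry is uncertain to that extent. The entries carry neither coordinates nor sequences in the tables, so no entry was placed in the genome, and piRNAs were not classed by location. The names used for individual piRNAs in the literature are not in the tables either. Segments had lengths and no names. They were assigned in order to chromosomes I, II, III, IV, V, X and mitochondrial DNA, because the 7 short last segments give lengths within which every gene annotated in Ensembl release 115 for WBcel235 ends. The authors' deposited table of totals gave total reads, genome-mapped reads and sense piRNA reads per library, which equalled the sums of the counts.

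Depth was 1022428 to 3121968 genome-mapped reads per library, and a floor of 3 counts stood for 0.961 to 2.93 RPM. Intervals and floors cover counting error only, since reads carried no molecular identifiers. Exact binomial intervals (Clopper-Pearson, 95%) are given for ratios of pooled rates with few reads, where a pooled rate is the summed reads of a group over its summed genome-mapped reads. The fits were tested on simulated data with known changes, built from the means, dispersions and library sizes of the tables. In them edgeR recovered 8.77% of 2-fold, 37.1% of 4-fold and 58.6% of 8-fold changes among 1067 piRNAs for PAZ-deletion against wild type, 5.00%, 21.2% and 74.1% for RNase-dead against wild type, and 4.76%, 34.4% and 61.0% for PAZ-deletion against RNase-dead, with 4.62%, 5.26% and 3.17% of calls false. Most 2-fold changes of a single piRNA were thus not detectable at this depth. All 2-fold changes of the 104 segments were recovered in each of the 3 comparisons.

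The total piRNA rate was sense piRNA reads per 1000000 genome-mapped reads (RPM), the scaling that the study design states. Pairs of groups were compared in totals, detected entries, mapping shares and chromosome shares by exact two-sided permutation tests of the difference of mean log2 values. Totals and chromosome shares were also compared over the 3 genotypes together by an exact permutation test of the F statistic on log2 values. With 3 libraries against 3 the smallest p is 0.1. The F tests of chromosome shares were adjusted over 7 chromosomes by the Benjamini-Hochberg method. Single piRNAs were tested on counts with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), with library sizes set to genome-mapped reads, all 9 libraries in 1 fit, and a Benjamini-Hochberg FDR of 0.05. The SE of an edgeR log2 fold change was its absolute value over the square root of that test's F, so it rests on the pooled spread. The SE of a log2 difference of totals came from the variances of the libraries in the groups compared. An entry was tested with at least 10 reads in total and a read in at least 3 libraries. Of 5252 entries with a sense read, 1067 passed, and they held 87.4% of sense reads. By library they held 86.4 to 89.5% in wild type and RNase-dead and 75.1 to 80.3% in PAZ-deletion, so the tested set covers PAZ-deletion less fully. Detected entries were counted after thinning to 1022428 genome-mapped reads, as a mean of 100 draws. A fold against a group with no read was computed against 3 counts over the group.

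Before the data were examined, the tests, the rule for named piRNAs and most alternatives were fixed. The tests of single genome segments and of antisense entries, and the denominator without the last segment of chromosome I, were chosen after the data were seen, as were chromosome shares without that segment, lists ranked by wild-type level, DESeq2 counts with the FDR over all entries and the replicate block in a fit of RNase-dead and wild type alone. The rule took the 10 most abundant by mean rate over all libraries, and for each pair of genotypes up to 8 decreases and 8 increases with the largest log2 fold change among those with FDR under 0.05, a mean of at least 20 counts per library in the higher group, and groups that did not overlap. By chance 10% of entries would show groups of 3 without overlap. The rule allowed 57 decreases and 2 increases for PAZ-deletion against wild type, 0 and 13 for RNase-dead against wild type, and 94 and 3 for PAZ-deletion against RNase-dead. A list of the 50 most abundant entries was also fixed.

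Pairing by replicate number was checked on the 76 entries with a mean of at least 20 counts. Deviations of same-numbered wild-type and RNase-dead libraries from their group means correlated at 0.28, 0.28 and 0.22. The numbers, which come from the titles, were therefore treated as pairing these libraries. The check cannot establish pairing, since differently numbered wild-type and PAZ-deletion libraries reached 0.21 and 0.20. Every result that uses the pairs rests on this assumption. Same-numbered PAZ-deletion libraries correlated with either group at -0.10 to -0.24, so they were not taken as paired. No libraries of a group agreed within sampling noise (chi-square per degree of freedom 1.61 to 3.31), and none was counted as a duplicate.

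Alternatives were other denominators, TMM scaling, library sizes from piRNA counts, DESeq2 with genome-mapped or median-ratio size factors, other count filters, fits of only the groups compared, a replicate block, a test against a fold of 1.5, other numbers of abundance classes and each library left out in turn. Agreement of the mutants was set beside 50 simulated sets in which all 9 libraries were drawn around a common mean, so that the error of the drawn controls is shared. That form was chosen after the result was seen, because a first form held the wild-type counts fixed, left out their error and gave a mean r of 0.02. Added later were sets with each library left out and sets in which same-numbered wild-type and RNase-dead libraries were drawn together at the mean correlation of those pairs, 0.26. DESeq2 by default gives no FDR to entries with a low mean, between 455 and 827 of the 1067 with genome-mapped size factors. Its counts were therefore also taken with a Benjamini-Hochberg FDR over all entries. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.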

Results

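Small RNAs were sequenced from whole adult hermaphrodites of Caenorhabditis elegans to compare piRNA levels between wild type and 2 mutants of prg-1, the gene for the Piwi-clade Argonaute that binds piRNAs in this species. The gene lies on chromosome I, bases 7585329 to 7588367 of the WBcel235 assembly, on the minus strand. In the RNase-dead mutant the label names a loss of the nuclease activity with which an Argonaute cuts its target, and in the PAZ-deletion mutant a loss of the PAZ domain, which in Argonautes holds the 3′ end of the guide RNA. Each of the 3 genotypes had 3 libraries, made 24 h after the middle of the fourth larval stage from 20 to 30 animals kept at 25 °C. Libraries held 1022428 to 3121968 reads mapped to the genome, and 1714 to 20802 sense reads mapped to piRNAdb, a database of piRNA sequences. The tables measured small RNAs and gave no level of the prg-1 transcript, so the genotype labels were not checked against the targeted gene.

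The total of sense piRNA reads was the measure that the study design put first. Wild-type animals had 4685 ± 1329 sense piRNA reads per 1000000 genome-mapped reads (RPM; SD, n = 3), RNase-dead animals 6144 ± 506 (SD, n = 3) and PAZ-deletion animals 1830 ± 143 (SD, n = 3). The 3 genotypes differed in this rate by an exact two-sided permutation test of the F statistic on log2 rates over 1680 assignments (p = 0.0071, where 0.0036 was the smallest p possible). PAZ-deletion libraries held 39.1% of the wild-type mean, a log2 difference of -1.32 ± 0.26 (SE), and all 3 lay below every wild-type library. They held 29.8% of the RNase-dead mean, a log2 difference of -1.75 ± 0.10 (SE), again without overlap. For both of these pairs the exact permutation p was 0.1, the smallest that 3 libraries against 3 can give. The RNase-dead mean was 131% of wild type, a log2 difference of 0.43 ± 0.26 (SE), which did not exceed the spread between replicates in the exact permutation test (p = 0.2). If libraries are paired by number, which was only assumed, RNase-dead was higher in all 3 pairs, at 6663 against 5930, 5653 against 3285 and 6115 against 4840 RPM. The exact sign-flip permutation p was 0.25, the smallest that 3 pairs allow. The difference of means was 0.19 without wild type replicate 2 and 0.62 without wild type replicate 1. With both mutants pooled against wild type, the log2 difference was -0.44 ± 0.47 (SE, exact permutation p = 0.464), since the mutants lay on opposite sides of wild type.

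**Figure D1:**
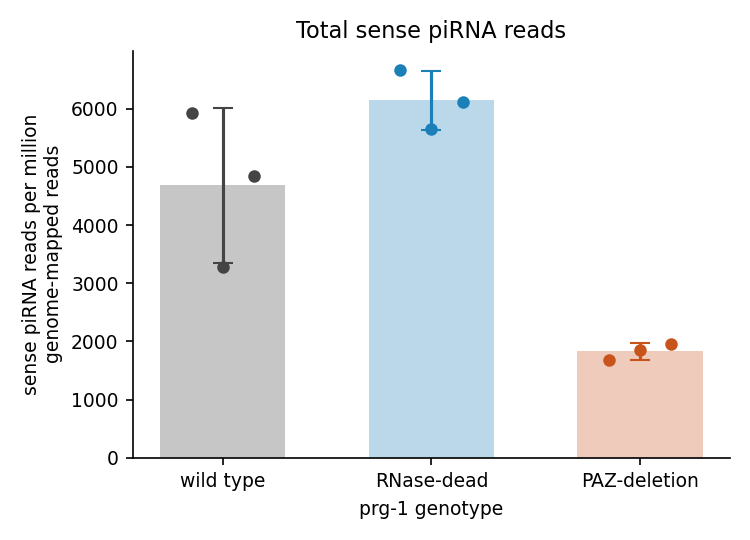
Sense piRNA RPM for each prg-1 genotype; bars are means, error bars SD and points the 3 libraries. PAZ-deletion libraries lie between 1676 and 1960, below the lowest wild-type library at 3285.

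The authors' deposited table gives the same means per genotype in its block of libraries, 4685 for wild type, 6144 for RNase-dead and 1830 for PAZ-deletion. In its block of genotypes the authors' deposited table lists a PAZ-deletion mean of 1896 with an SD of 996, although its percentage of wild type, 39.1 ± 3.05, belongs to the mean of 1830. The share of reads mapped to the genome was 94.5% in wild type, 95.4% in RNase-dead and 93.9% in PAZ-deletion, and no pair differed beyond replicate spread (exact permutation p = 0.2 to 0.5, n = 3 per group).

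In PAZ-deletion animals most of the abundant piRNAs were far lower than in wild type, while a few were not. The most abundant entry, cel-piR-10036, was at 491 ± 89.1 RPM in wild type and 11.2 ± 6.52 in PAZ-deletion (SD, n = 3; log2 fold change -5.37 ± 0.39 SE, edgeR FDR 2.46e-39). Next in abundance, cel-piR-6101 fell by 4.59 on the log2 scale, and cel-piR-2077 was 16.2-fold lower by pooled rate, the reads of 3 libraries over their genome-mapped reads. Together these 3 entries made up 20.8 ± 2.25% of sense piRNA reads in wild type and 1.84 ± 0.706% in PAZ-deletion (SD, n = 3, exact permutation p = 0.1). Among the 10 most abundant entries, cel-piR-7578, cel-piR-8214, cel-piR-6252 and cel-piR-9316 also fell, with log2 fold changes of -4.81, -4.19, -3.37 and -2.17. The other 3 were not called, and cel-piR-12706 was at 55.7 ± 13.4 in wild type and 72.2 ± 15.7 in PAZ-deletion, cel-piR-156 at 29.2 ± 13.2 and 53.8 ± 9.81, and cel-piR-9221 at 29.8 ± 14.3 and 22.98 ± 11.5 RPM (SD, n = 3). This list ranks by the mean over all 9 libraries, so a fall in PAZ-deletion lowers the rank of an entry. Ranked by wild-type level instead, 9 of the 10 most abundant were lower, and cel-piR-12706 alone was not called.

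**Figure D2:**
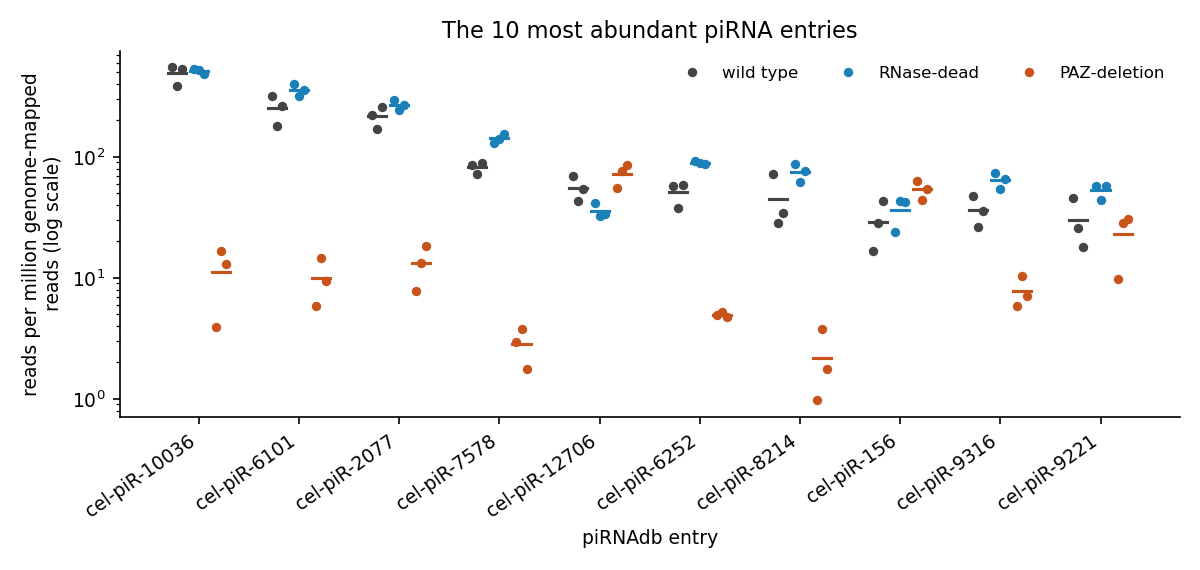
RPM on a log scale for the 10 piRNAdb entries with the highest mean over 9 libraries; points are libraries and short lines are means of 3. In PAZ-deletion, cel-piR-10036 lies near 11.2 against 491 in wild type, while cel-piR-12706 lies at 72.2 against 55.7.

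Of 1067 piRNAs tested, 205 were lower and 14 higher in PAZ-deletion than in wild type (edgeR FDR under 0.05), and the median log2 fold change was -1.25, or -0.83 with the 219 entries that had no read in a group set to a floor of 3 counts. The count filter kept 75.1 to 80.3% of sense reads in PAZ-deletion libraries and 86.4 to 87.8% in wild type, so these counts cover PAZ-deletion less fully. Of the 50 most abundant, 35 were lower, 2 higher and 13 neither, or 38 lower and 4 higher when adjusted over the list alone. Membership of that list depends in part on the change itself, as for cel-piR-14240, which enters through its PAZ-deletion level. Of the 50 most abundant by wild-type level, 38 were lower, 0 higher and 12 neither. The largest decreases among entries that met the naming rule included cel-piR-3162, with 323 reads in the 3 wild-type libraries and 0 in PAZ-deletion, at least 75.2-fold lower. No PAZ-deletion read was counted for cel-piR-2717, cel-piR-15599, cel-piR-216, cel-piR-9721 and cel-piR-1694 either, which were at least 28.2-fold, 28.6-fold, 19.8-fold, 15.4-fold and 15.1-fold lower, with a floor of 3 counts over the group. A lone PAZ-deletion read was counted for cel-piR-238 against 351 in wild type, a ratio of pooled rates of 245 with a counting interval of 43.7 to 9714. The same was so for cel-piR-3464 against 133 reads, a ratio of pooled rates of 92.9 with an interval of 16.4 to 3698. Only 2 entries met the rule for an increase, cel-piR-14240 and cel-piR-1592. The first was at 2.09 ± 1.26 RPM in wild type and 95.3 ± 43.3 in PAZ-deletion (SD, n = 3; log2 fold change 5.36 ± 0.47 SE, edgeR FDR 7.88e-27). The second was at 11.8 ± 2.55 and 29.6 ± 7.30, a log2 fold change of 1.29 (edgeR FDR 0.0131), and was not called without PAZ-deletion replicate 1.

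The share of piRNAs called in PAZ-deletion was highest among abundant ones. When the tested piRNAs were ranked by mean rate over all 9 libraries into 5 classes, 116 of the 214 most abundant were lower and 3 higher, and the summed rate of that class was 922 ± 90.4 against 3102 ± 806 RPM in wild type (SD, n = 3). In the least abundant class of 213, edgeR called 0, with 28 lower and 4 higher at an unadjusted p under 0.05. DESeq2 with genome-mapped size factors gave none of the 213 an FDR, and had 0 lower and 1 higher at an unadjusted p under 0.05. The summed rate of that class was 52.8 ± 11.2 against 120 ± 41.5 (exact permutation p = 0.1 for both classes). Mean rates in the least abundant class were 0.400 to 0.616 RPM, below the floor of 3 counts in every library. Calls were hardly possible there, so the share called does not measure the size of the change. From the most to the least abundant class, 55.6%, 28.2%, 11.2%, 7.51% and 0.0% were called, but the summed rates, at 29.7%, 46.8%, 61.7%, 60.3% and 44.1% of wild type, did not follow that order. In the classes at 61.7% and 60.3% they overlapped wild type (exact permutation p = 0.3 and 0.2, n = 3 per group). The 44.1% is shaped by the count filter. At such low rates an entry reached 10 reads more easily through the deeper libraries, and PAZ-deletion libraries were the shallowest on average. With 10 classes, the least abundant was at 28.0% of wild type in PAZ-deletion and 147% in RNase-dead. The next class was at 57.6% and 121%. Entries below the count filter summed to 392 RPM in PAZ-deletion and 599 in wild type (exact permutation p = 0.2, n = 3 per group). After every library was thinned to 1022428 genome-mapped reads, 834 ± 21.2 entries had a read in PAZ-deletion, 1226 ± 276 in wild type and 1393 ± 73.1 in RNase-dead (SD, n = 3). Every PAZ-deletion library had fewer than any other library (exact permutation p = 0.1 against either group), while RNase-dead and wild type did not differ beyond replicate spread (exact permutation p = 0.5). Unthinned, the numbers were 1091, 1892 and 2211. Thinning set genome-mapped reads equal and not piRNA reads, so the lower piRNA total in PAZ-deletion can by itself lower the number detected. Detection at equal piRNA reads was not compared.

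The PAZ-deletion calls split otherwise when the scaling was taken from the piRNA reads themselves, which removes all or part of a change common to all piRNAs. With library sizes set to the sum of piRNA counts, 78 piRNAs were higher and 75 lower, 51.0% higher against 6.39% with genome-mapped reads, and the median log2 fold change was -0.02. DESeq2 with median-ratio size factors called 28 higher and 84 lower, 25.0% higher, with a median of -0.47. Without PAZ-deletion replicate 2, edgeR called 133 piRNAs with genome-mapped reads, 9 higher and 124 lower, and without wild type replicate 1 it called 9 higher and 146 lower. The entry cel-piR-156 was called higher without wild type replicate 3, at a log2 fold change of 1.28. With library sizes from piRNA counts, which shift every piRNA together, the log2 fold change of cel-piR-9221 went from -0.34 to 1.03, and cel-piR-156 and cel-piR-12706 were called higher.

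**Figure D3:**
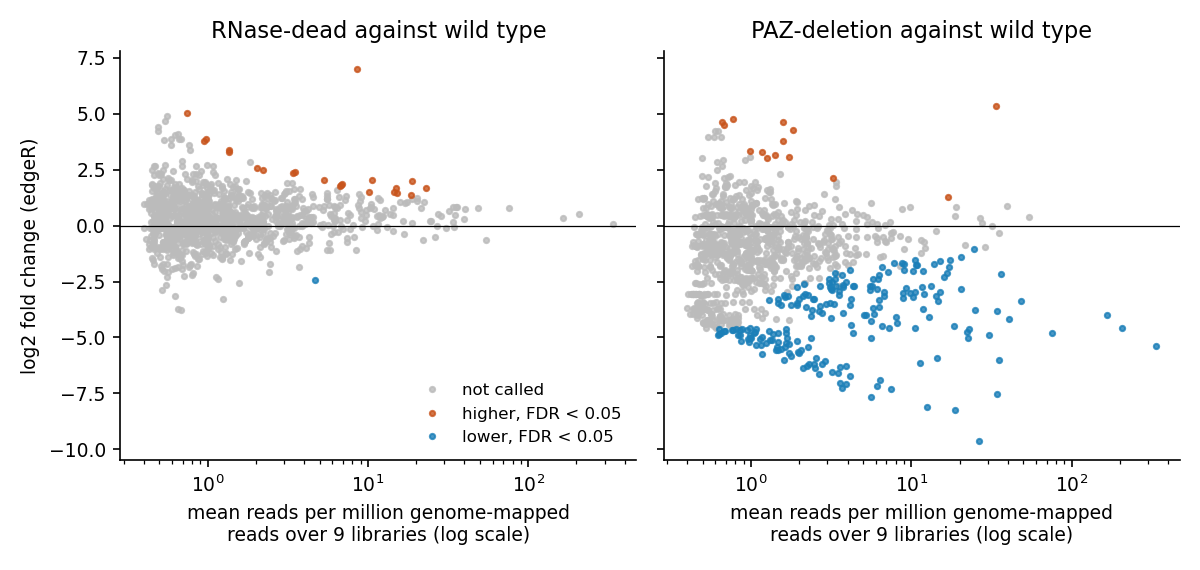
Log2 fold change from edgeR against mean RPM (log scale) for 1067 piRNAs, RNase-dead against wild type on the left and PAZ-deletion against wild type on the right; coloured points have FDR under 0.05. On the right 205 piRNAs are lower and 14 higher, and on the left 1 is lower and 22 are higher.

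In RNase-dead animals, 56 of the 76 entries with a mean of at least 20 counts had a fitted level within 2-fold of wild type, and 20 lay above that. The entry cel-piR-10036 was at 512 ± 23.5 RPM in RNase-dead and 491 ± 89.1 in wild type (SD, n = 3). Of the 10 most abundant, edgeR called 0, with 5 higher at an unadjusted p under 0.05, and DESeq2 with genome-mapped size factors called 1 higher, cel-piR-7578, or 0 with the FDR taken over all 1067 entries. With median-ratio size factors DESeq2 called 1 lower, cel-piR-12706, and 0 higher, with 2 lower and 0 higher at an unadjusted p under 0.05. Their log2 fold changes ranged from -0.63 for cel-piR-12706 to 0.83 for cel-piR-9221. By edgeR, 22 piRNAs were higher and 1 lower than in wild type at FDR under 0.05, with a median log2 fold change of 0.32. Over the 104 genome segments the median was 0.29, so a rise of this size was not particular to piRNAs. The piRNA with the largest increase was cel-piR-13631, with 1 read in the 3 wild-type libraries and 194 in RNase-dead, a ratio of pooled rates of 177 with a counting interval of 31.4 to 7027 (edgeR FDR 7.01e-17). The other 7 under the naming rule rose less. Of these, cel-piR-4274 was at 16.1 ± 4.90 and 52.6 ± 3.83 RPM, cel-piR-11525 at 8.64 ± 4.43 and 35.6 ± 6.49, and cel-piR-715 at 5.68 ± 2.77 and 24.3 ± 11.4 (SD, n = 3). The log2 fold changes of cel-piR-12731, cel-piR-5151, cel-piR-3035 and cel-piR-3008 lay between 1.75 and 2.03. The piRNA called lower was cel-piR-8767, named after its values were seen, with a log2 fold change of -2.41 ± 0.63 (SE, edgeR FDR 0.0230), from 56 reads in wild type to 11.

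Single libraries decided several of these calls. Those of cel-piR-12731, cel-piR-3035 and cel-piR-3008 were lost without wild type replicate 2 or 3 or any RNase-dead library, that of cel-piR-5151 without wild type replicate 2 or 3 or RNase-dead replicate 1 or 3, and those of cel-piR-4274 and cel-piR-715 without RNase-dead replicate 3. Without wild type replicate 1, cel-piR-9221 and cel-piR-8214 were called higher, with log2 fold changes of 1.30 and 1.25.

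Among the 50 most abundant, edgeR called 6 higher and 0 lower in RNase-dead, or 14 higher and 0 lower when adjusted over the list alone. At an unadjusted p under 0.05, 21 were higher and 0 lower, and DESeq2 with genome-mapped size factors called 11 higher and 0 lower, or 4 higher and 0 lower with the FDR over all entries. With median-ratio size factors DESeq2 called 2 higher and 1 lower, with 10 higher and 6 lower at an unadjusted p under 0.05. The 6 became 14, 3 and 3 without wild type replicates 1, 2 and 3, and 2, 3 and 1 without RNase-dead replicates 1, 2 and 3. The count of 23 calls moved with single libraries, to 46 without wild type replicate 1, 9 without wild type replicate 2, 6 without wild type replicate 3, and 4, 8 and 2 without RNase-dead replicates 1, 2 and 3. Same-numbered libraries of these groups were assumed to be paired, and with the replicate number as a block in a fit of the 2 groups edgeR called 44 piRNAs, 42 higher and 2 lower. The same fit without the block called 29, 27 higher and 2 lower, and the block in the fit of all 9 libraries gave 20. Scaling changed the split from 95.7% higher to 76.9% with TMM factors (10 higher, 3 lower), 58.8% with library sizes from piRNA counts (10 higher, 7 lower) and 75.0% with DESeq2 median-ratio factors (3 higher, 1 lower). The last segment of chromosome I, which holds 4 annotated ribosomal RNA genes, took 10.1 ± 5.54% of genome-mapped reads in wild type and 2.27 ± 0.546% in RNase-dead (SD, n = 3, exact permutation p = 0.1), and without it in the denominator 6 piRNAs were higher and 1 lower.

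The mutants were also compared directly. Of 1067 piRNAs, 296 were lower and 11 higher in PAZ-deletion than in RNase-dead (edgeR FDR under 0.05), with a median log2 fold change of -1.69, or -1.10 with the 210 entries that had no read in a group set to the floor. Among the 50 most abundant, 40 were lower, 3 higher and 7 neither, or 41 lower and 3 higher when adjusted over the list alone. Of the 10 most abundant, cel-piR-10036, cel-piR-6101, cel-piR-2077, cel-piR-7578, cel-piR-8214, cel-piR-6252 and cel-piR-9316 fell by 2.99 or more on the log2 scale, and cel-piR-12706 rose from 35.9 ± 5.01 to 72.2 ± 15.7 RPM (SD, n = 3; log2 fold change 1.01, edgeR FDR 0.0178). The change in cel-piR-9221, a log2 fold change of -1.17 with edgeR FDR 0.00879, went to 0.57 with library sizes from piRNA counts and to 0.03 with DESeq2 median-ratio factors, scalings that shift every piRNA together. The entry cel-piR-156 was not called. For 7 of the 8 largest decreases no PAZ-deletion read was counted, and these were cel-piR-2717, cel-piR-3162, cel-piR-13631, cel-piR-15599, cel-piR-9721, cel-piR-1159 and cel-piR-4757. They were at least 64.6-fold to at least 16.1-fold lower. The eighth, cel-piR-238, had 1 read against 402. The increases were in cel-piR-14240, at 4.08 ± 1.38 and 95.3 ± 43.3 RPM, cel-piR-1592, at 9.21 ± 2.69 and 29.6 ± 7.30, and cel-piR-12706 (SD, n = 3). Scaling moved the split from 3.58% higher to 14.3% with TMM factors, 54.0% with library sizes from piRNA counts and 27.1% with DESeq2 median-ratio factors, and without PAZ-deletion replicate 2 edgeR called 194, 7 higher and 187 lower. The call of cel-piR-12706 was lost without RNase-dead replicate 2 or 3 or PAZ-deletion replicate 2 or 3, and that of cel-piR-9221 without PAZ-deletion replicate 1.

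Taking the mean of the mutants against wild type, 91 piRNAs were lower and 5 higher by edgeR, 5.21% higher against 29.6% with library sizes from piRNA counts. When the mutants were instead fitted as 1 group of 6 libraries, edgeR called 0 piRNAs at FDR under 0.05 and 53 at an unadjusted p under 0.05, while DESeq2 with genome-mapped size factors called 65 in the fit of 3 groups, or 53 with the FDR over all entries. Without PAZ-deletion replicate 3 the count was 63. In both mutants against wild type and in the same direction, edgeR called 0 piRNAs, where independent lists would share 0.192 lower and 0.289 higher. At an unadjusted p under 0.05, 13 were lower and 13 higher in both. DESeq2 with genome-mapped size factors left 827 of 1067 without an FDR in at least 1 comparison, so few shared calls were possible, and 2 were lower and 3 higher in both at an unadjusted p under 0.05. With median-ratio size factors, which left 538 without an FDR, it called 1 higher, cel-piR-11525, and 0 lower, with 2 higher and 13 lower at an unadjusted p under 0.05. With the FDR taken over all 1067 entries these fits called 0, and 1 higher and 0 lower. Across the 1067 piRNAs, which are not independent replicates, the log2 fold changes of the mutants had a Pearson r of 0.28 and a Spearman rho of 0.22. In 50 simulated sets of unchanged groups that share their controls, with all libraries drawn independently, r was 0.45 on average and 0.38 to 0.53 in range. The observed covariance was 0.66, against a simulated mean of 0.48 and range of 0.39 to 0.64. With same-numbered wild-type and RNase-dead libraries drawn together, the simulated r was 0.41 on average and 0.34 to 0.47 in range, and the covariance 0.37 and 0.30 to 0.46. The observed r thus lay below both ranges and the observed covariance above both. The simulated groups carried no change, while PAZ-deletion fold changes spread widely, with an SD of 2.44 among entries with a mean of at least 20 counts. Changes in PAZ-deletion alone lower r, so an r below the range does not decide whether the mutants share changes. When each library was left out of the data and of independent draws alike, r stayed below the simulated range in all 9 cases, while the covariance depended on the library. It lay above the range without wild type replicate 1 or 3 or PAZ-deletion replicate 2 or 3, at 1.12, 1.16, 0.59 and 0.61 against at most 0.91, 1.14, 0.58 and 0.60. It lay within the range without wild type replicate 2, at 0.77, without PAZ-deletion replicate 1, at 0.56, and without any 1 RNase-dead library, at 0.46 to 0.51. With 3 wild-type libraries the controls could not be split, and both fold changes rest on the same controls. For the 76 entries with a mean of at least 20 counts r was 0.08, against a simulated mean of 0.49 and range of 0.23 to 0.68, and the covariance was 0.19, against a simulated mean of 0.09 and range of 0.03 to 0.14. With the pairs drawn together those ranges were 0.23 to 0.63 and 0.03 to 0.13.

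Chromosome IV holds 14714 of 15363 annotated piRNA genes of WBcel235, so its share of genome-mapped reads was taken as a further readout. That share was 14.0 ± 1.98% in wild type, 15.6 ± 0.290% in RNase-dead and 15.6 ± 0.0738% in PAZ-deletion (SD, n = 3). The exact permutation p of the F statistic over the 3 genotypes, adjusted over 7 chromosomes, was 0.075, and adjusted p given below are of this test. Between pairs of genotypes no adjusted exact permutation p of the difference of means was under 0.15 for any chromosome. The 8 segments of chromosome IV with at least 200 piRNA genes took 7.19 ± 1.23%, 7.41 ± 0.139% and 8.94 ± 0.624% of reads, and every PAZ-deletion library lay above every wild-type library (exact permutation p = 0.1). Sense piRNA reads were at most 0.666% of genome-mapped reads in any library. The genotypes differed for chromosome I, at 30.9 ± 4.74%, 25.7 ± 1.64% and 22.3 ± 1.79% (adjusted exact permutation p = 0.0417), for chromosome III, at 15.1 ± 2.30%, 18.4 ± 0.795% and 20.6 ± 1.28% (0.0125), and for mitochondrial DNA, at 0.522 ± 0.0468%, 0.399 ± 0.0293% and 0.730 ± 0.106% (0.0125), each in the order wild type, RNase-dead and PAZ-deletion (SD, n = 3). For chromosome I, part of the difference came from its last segment. Without it chromosome I held 23.1 ± 2.13%, 24.0 ± 1.55% and 18.6 ± 1.20% of the remaining reads in that order (SD, n = 3, adjusted exact permutation p = 0.03). The RNase-dead mean thus no longer lay below the wild-type mean. For that pair the exact permutation p was 0.6, and with the segment it was 0.2, so the groups were not separated there either. Of all genome-mapped reads the rest of chromosome I took 20.8%, 23.5% and 17.7%. Without that segment chromosome IV was at 15.5%, 16.0% and 16.4% (adjusted exact permutation p = 0.768), and its 8 segments with piRNA genes at 7.99%, 7.58% and 9.38%, where PAZ-deletion overlapped wild type (exact permutation p = 0.3, n = 3 per group). The adjusted exact permutation p became 0.025 for chromosome III and mitochondrial DNA and 0.03 for V and X. Chromosome X was at 9.22 ± 1.41%, 9.35 ± 0.272% and 12.9 ± 1.16%, chromosome II at 16.9 ± 1.504%, 18.2 ± 0.441% and 15.4 ± 1.16%, and chromosome V at 13.4%, 12.3% and 12.4%, with adjusted exact permutation p of 0.055, 0.0857 and 0.055. The calls for chromosomes I and III were lost when any mutant library was left out, and that for chromosome I also without wild type replicate 2, with adjusted exact permutation p up to 0.105 and 0.0917. Chromosome X was called without wild type replicate 1, 2 or 3 (adjusted exact permutation p = 0.04, 0.025 and 0.04), chromosome II without wild type replicate 1 (0.04) and chromosome IV without wild type replicate 3 (0.04). For mitochondrial DNA the adjusted exact permutation p was 0.05 without any 1 of the RNase-dead libraries.

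**Figure D4:**
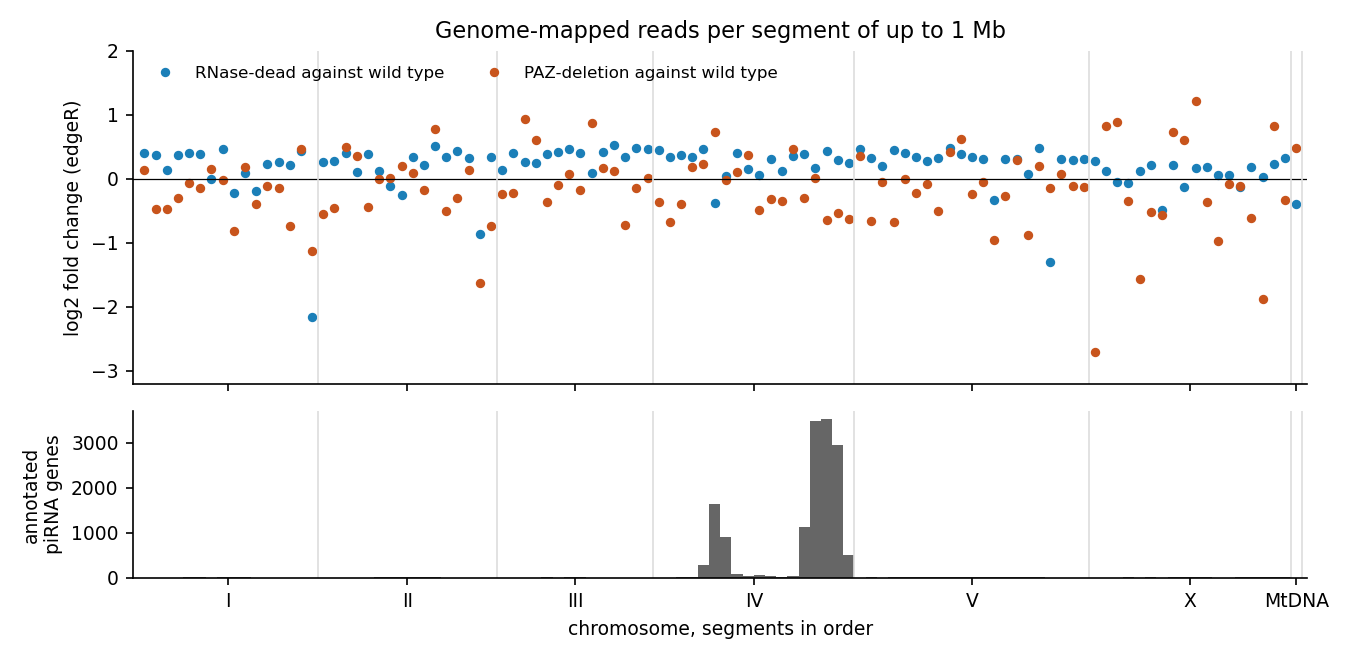
Log2 fold change from edgeR of genome-mapped reads in 104 segments of up to 1000000 bases in chromosome order, RNase-dead and PAZ-deletion each against wild type, above the number of annotated piRNA genes per segment. The piRNA genes lie mainly in 8 segments of chromosome IV, and the lowest PAZ-deletion point is the first segment of X at -2.70.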

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

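Chosen only after the result was seen were the tests of single genome segments and of antisense entries, the test of counting noise and both tests of the X segments. The ratio of antisense to sense reads, single antisense entries and single segments lay above wild type in a mutant, which is why they are given here.

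Antisense reads on piRNAdb entries stood higher relative to sense reads in PAZ-deletion, at 21.1 ± 2.41 per 100 sense reads against 11.1 ± 1.57 in wild type and 8.45 ± 0.688 in RNase-dead (SD, n = 3, exact permutation p = 0.1 for each pair). By rate they were lower than in wild type, so the ratio rose with the larger fall of sense reads: they were at 384 ± 26.0 RPM in PAZ-deletion, 509 ± 88.9 in wild type and 517 ± 3.97 in RNase-dead (SD, n = 3). Of 127 antisense entries tested, edgeR called 2 higher and 20 lower in PAZ-deletion than in wild type. The 2 were cel-piR-11247, with 0 antisense reads in wild type and 21 in PAZ-deletion, and cel-piR-1276, with 1 and 14. Without PAZ-deletion replicate 3 the counts were 1 higher and 9 lower, and without PAZ-deletion replicate 2 they were 3 higher and 10 lower.

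Of 104 genome segments, edgeR called 18 higher and 29 lower in PAZ-deletion than in wild type, or 33 higher and 31 lower with TMM factors. Without PAZ-deletion replicate 2, 11 segments were higher and 26 lower, and without wild type replicate 3, 20 were higher and 19 lower. Without wild type replicate 1, 12 were higher and 24 lower. In RNase-dead, 12 segments were higher and 4 lower than in wild type. With the replicate number as a block in the fit of all libraries, edgeR called 0 higher and 2 lower, with 33 higher and 5 lower at an unadjusted p under 0.05. That fit also blocks the PAZ-deletion libraries, which were not taken as paired. A blocked fit of RNase-dead and wild type alone was not run on segments. With TMM factors edgeR called 0 segments, with 17 higher and 14 lower at an unadjusted p under 0.05. Without wild type replicate 3, 55 were higher in RNase-dead, and without any other wild-type or RNase-dead library 0 were, with 13 to 28 higher at an unadjusted p under 0.05. No other tool was run on the segments.

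The first pattern weighed is the uneven fall in PAZ-deletion. Of the 76 entries with a mean of at least 20 counts, 54 were called lower, summing to 2038 ± 485 RPM in wild type and 155 ± 26.8 in PAZ-deletion, while 16 were not called and lay within 2-fold, at 320 ± 75.8 and 350 ± 53.1 (SD, n = 3). Of the 80 entries with such a mean in wild type alone, 59 were called lower, and 17 were not called and lay within 2-fold. Counting noise around a common fall is argued against, because 14.3% of tested piRNAs were still called with library sizes set to piRNA totals, above the 5% it allows. Whether the entries that did not fall hold reads of other RNAs stays open: the log2 differences of RNase-dead from wild type were 0.49 for the fallen and 0.48 for the others, but their difference of 0.0028 had an interval of -0.40 to 0.41, too wide to decide. An effect of the genotype that spares some piRNAs may also explain the pattern, and it was not tested.

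The second pattern is the higher total piRNA rate in RNase-dead, 131% of wild type, which did not pass its own exact permutation test (p = 0.2, n = 3 per group). Reads of ribosomal RNA genes in the denominator could account for part of it. Without the last segment of chromosome I the ratio was 1.21 (exact permutation p = 0.3), which is 33.5% of the way to a ratio of 1. That value lies between the bounds set for and against this explanation, so it stays open, as does an effect of the genotype. The rise was not particular to piRNAs. In RNase-dead against wild type the median log2 fold change was 0.29 over the 104 genome segments and 0.32 over the 1067 piRNAs. With TMM factors these medians were 0.02 and 0.04. A shift in the make-up of the genome-mapped reads can thus not be told apart from a rise of piRNAs.

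The third pattern is the fall of 3 segments of X in PAZ-deletion. The segment from base 1 to 1000000 fell from 3431 ± 653 to 526 ± 52.1 RPM, that from 15000001 to 16000000 from 2877 ± 507 to 786 ± 38.5, and that from 4000001 to 5000000 from 1822 ± 371 to 617 ± 62.5 (SD, n = 3). A loss of piRNA reads mapped there is argued against, because these segments together lost 3346 ± 1169 RPM (SE) more than all sense piRNA reads did. Scaling by genome-mapped reads is argued against too, since the smallest of the 3 falls was still -1.43 on the log2 scale with TMM factors. Secondary siRNAs or microRNAs of these segments may have fallen with the genotype, a hypothesis that counts per segment could not test.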

How the results depend on the processing

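The settings with segments and antisense entries, the denominator without the last segment of chromosome I and the replicate block in a fit of RNase-dead and wild type alone were chosen after the data were seen. Log2 differences of the total rate kept their direction in every denominator, with linear rates and with each library left out, at 0.19 to 0.62 for RNase-dead against wild type, -1.55 to -1.13 for PAZ-deletion against wild type, -1.81 to -1.69 for PAZ-deletion against RNase-dead and -0.68 to -0.24 for both mutants when libraries were left out. The exact permutation p of the 3 genotypes together stayed at 0.0036 to 0.0143. The pairwise tests of 3 against 3 cannot pass 0.05, so their side of the threshold says nothing about stability. Leaving out a library leaves its group 2.

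For piRNAs called in RNase-dead against wild type, 23 became 13 with TMM factors, 4 with DESeq2 median-ratio factors, 5 with no low-count filter, 3 with glmTreat above a fold of 1.5, 12 without chromosome I and mitochondrial DNA, 7 without the last segment of chromosome I, and 2 to 46 with libraries left out. For PAZ-deletion against wild type, 219 became 112 with median-ratio factors, 140 with no filter, 146 with a stricter filter and 133 to 249 with libraries left out. For PAZ-deletion against RNase-dead, 307 became 174 with library sizes from piRNA counts, 133 with median-ratio factors, 202 with no filter, 180 with a stricter filter and 194 to 272 with libraries left out. For both mutants, 96 became 57 with median-ratio factors, 55 with no filter, 60 with glmTreat, 63 to 114 with libraries left out, and 0 by edgeR with the mutants as 1 group, where 53 had an unadjusted p under 0.05. DESeq2 was not run in that last form. The stricter filter and the fits with libraries left out test fewer piRNAs, and DESeq2 median-ratio fits left 538, 579 and 497 of 1067 without an FDR in the last 3 comparisons. The causes were not tested. With the FDR over all entries, chosen after the data were seen, DESeq2 called 6, 138, 191 and 53 with genome-mapped factors and 4, 95, 110 and 49 with median-ratio factors, in the same order. Scaling moved the median log2 fold change from 0.32 to 0.04 (TMM), -0.03 (piRNA counts) and -0.08 (median ratio) in RNase-dead against wild type, from -1.25 to -0.93, -0.02 and -0.47 in PAZ-deletion against wild type, and from -1.69 to -1.09, -0.10 and -0.53 between the mutants.

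With the replicate number as a block in the fit of all libraries, edgeR called 20, 169, 257 and 70 piRNAs for these comparisons, in the same order. In the fit of RNase-dead and wild type alone, whose libraries were assumed to be paired by number, the block gave 44 piRNAs and 19 of the 50 most abundant, against 29 and 8 in that fit without it. For segments in RNase-dead against wild type the block, run only in the fit of all libraries, changed 12 higher and 4 lower to 0 higher and 2 lower. In PAZ-deletion against wild type, where no pairing was assumed, 14 piRNAs called higher became 9. It moved no other total of calls by over 1.5 times. Blocked log2 differences of the totals equal the unblocked ones, with an exact sign-flip p of 0.25, the smallest that 3 pairs allow.

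Segments called in RNase-dead against wild type were 0 with TMM factors, where 31 had an unadjusted p under 0.05, and 3 to 60 with libraries left out. They were 36 to 53 in PAZ-deletion against wild type and 55 to 73 against RNase-dead. Antisense entries called were 0 to 1, 10 to 21 and 14 to 23 for these comparisons, and the 0, without wild type replicate 2, had 8 at an unadjusted p under 0.05. In the most abundant of 10 classes 67.3% and 80.4% were called in PAZ-deletion against wild type and against RNase-dead. With libraries left out, the most abundant of 5 classes had 0.935 to 17.3% called in RNase-dead against wild type, 44.4 to 59.3% in PAZ-deletion against wild type and 61.2 to 67.3% between the mutants. Of the 50 most abundant, 6 called in RNase-dead against wild type became 11 by DESeq2 with genome-mapped factors, 3 with median-ratio factors, 3 with no filter, 1 with glmTreat, 3 without the last segment of chromosome I, and 1 to 14 with libraries left out. In PAZ-deletion they ranged from 34 to 39 against wild type and 40 to 43 against RNase-dead.

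Adjusted exact permutation p of chromosomes V and X fell to 0.0298 without chromosome I and mitochondrial DNA and to 0.03 without the last segment of chromosome I, where that of IV rose to 0.768. With libraries left out they ranged over 0.0125 to 0.105 for I, 0.04 to 0.2 for II, 0.0125 to 0.0917 for III, 0.04 to 0.286 for IV, 0.0625 to 0.13 for V, 0.025 to 0.0917 for X and 0.0167 to 0.05 for mitochondrial DNA. The correlation of the mutants' fold changes was 0.084 with a mean of at least 20 counts and 0.195 to 0.412 with libraries left out. Log2 differences in detected entries were 0.03 to 0.36, -0.71 to -0.38 and -0.77 to -0.70, and those in mapped shares 0.0073 to 0.0208, -0.0199 to -0.0033 and -0.0337 to -0.0186, for RNase-dead against wild type, PAZ-deletion against wild type and PAZ-deletion against RNase-dead.

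Among the named piRNAs, direction reversed for cel-piR-9221: PAZ-deletion against RNase-dead gave 0.57 with library sizes from piRNA counts and 0.0303 with median-ratio factors, and PAZ-deletion against wild type gave 1.03 with library sizes from piRNA counts. These scalings shift every piRNA together, as the medians show, so the reversals follow from the scaling. Calls of named piRNAs held in 102 of 144 alternative values in RNase-dead against wild type, 284 of 288 in PAZ-deletion against wild type and 311 of 323 between the mutants. Classes by genome location were not run, since entries carry no coordinates, and a pseudocount was not varied, since counts were tested. At this depth most 2-fold changes of a single piRNA would be missed.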

Other observations

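All tests of single segments and antisense entries given here were chosen after the data were seen, as were the second form of the splits for both mutants and the splits that part pairs. In PAZ-deletion the segments of chromosome IV that hold piRNA genes did not move as a group. The 8 segments with at least 200 such genes took 8.94% of genome-mapped reads in PAZ-deletion. Sense piRNA reads were at most 0.196% in any of its libraries. Most reads of these segments thus came from other RNAs, and their changes do not measure piRNAs by locus. The segment from base 5000001 to 6000000, with 1638 annotated piRNA genes, was higher than in wild type (log2 fold change 0.73, edgeR FDR 0.00574), while that from 15000001 to 16000000, with 3519, that from 16000001 to 17000000, with 2950, and that from 17000001 to the end, with 502, were lower (-0.64, -0.53 and -0.63). The segment from 14000001 to 15000000, with 3476, was not called (edgeR FDR 0.959). The largest increase of any segment was on X from 9000001 to 10000000, from 4504 ± 971 to 10408 ± 2300 RPM (SD, n = 3; log2 fold change 1.21, edgeR FDR 1.95e-11). In chromosome III from 2000001 to 3000000 and X from 2000001 to 3000000 the log2 fold changes were 0.94 and 0.89. In RNase-dead the largest falls were in the last segment of chromosome I, at -2.15, and in chromosome V from 17000001 to 18000000, which holds 15 annotated ribosomal RNA genes, at -1.29 (edgeR FDR 8.97e-06).

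Among antisense entries, cel-piR-1090 had 196 reads in wild type, 181 in RNase-dead and 0 in PAZ-deletion, and cel-piR-6514 had 69, 81 and 0. For cel-piR-1259 the antisense reads were 232, 160 and 1. Antisense cel-piR-1599 was at 64.4, 38.6 and 110 RPM in the order wild type, RNase-dead and PAZ-deletion and was not called (edgeR FDR 0.1202 for PAZ-deletion against wild type). In RNase-dead the antisense entry called lower than in wild type was cel-piR-14696, with 12 reads against 86, and wild type was at 14.8 ± 14.2 RPM (SD, n = 3). Without wild type replicate 2, edgeR called 0 antisense entries in RNase-dead, with 8 at an unadjusted p under 0.05, and no other tool was run on antisense entries.

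Other splits of the samples were counted for each number of calls. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In PAZ-deletion against wild type 1 of 10, the real split, gave as many piRNAs, 219 against at most 0 elsewhere. The same held for PAZ-deletion against RNase-dead, 307 against 0, and for RNase-dead against wild type, 23 against 1. For segments the real and highest other counts were 47 and 0 in PAZ-deletion against wild type, 70 and 0 in PAZ-deletion against RNase-dead, and 16 and 2 in RNase-dead against wild type, each with 1 split as large. Antisense entries gave 22 and 0, 26 and 0, each with 1 split as large, and in RNase-dead against wild type 1 and 1, with 4 of 10 splits as large.

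For both mutants against wild type, 5 of 100 drawn assignments gave at least the real 96 piRNAs, so a chance assignment was not excluded there. The draws also reshuffle the PAZ-deletion libraries, whose own change can give calls in other assignments. The share of 5 in 100 is therefore not a chance rate and cannot decide the question. The highest other assignment called 258 and had the PAZ-deletion libraries as its first group, which points to a structure of the samples, with PAZ-deletion apart from the rest. This procedure was chosen after a first one had been seen, a fit of 6 libraries against 3. There edgeR called 0 piRNAs for the real split, 53 at an unadjusted p under 0.05, and 273 with the PAZ-deletion libraries apart. Since no count can be below 0, it was fixed that 84 of 84 splits were as large, which says nothing about chance. Wild-type and RNase-dead libraries with the same number were taken as pairs, and the real split was set beside the other 3 splits that part all pairs. The real one called 29 piRNAs without a block and 44 with it, and edgeR called 0 in each of the other 3, where libraries of both genotypes stood on each side.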
